A study of Populus x canadensis with 9 samples.

How the data were processed

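Shoot apical meristems of 'Carpaccio', a hybrid between Populus deltoides and P. nigra, were profiled on 1-colour Agilent oligonucleotide arrays. Per the labels' protocols, each of 3 water treatments had 3 arrays, each from the separately extracted RNA of a single plant. RNA had an integrity number of at least 8, and 80 ng per sample were amplified and labelled with cyanine 3. The replicates are therefore separate plants.

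The deposited scanner files hold a linear fluorescence intensity for each of 53546 spots, written by Agilent Feature Extraction 10.7.3.1, per the file headers. The processed intensity in these files was background-subtracted and spatially detrended by the authors' scanner software, per the file headers, and was not scaled between arrays. The authors also deposited a table of log2 values for the same arrays, with scaling and centring unstated. For the 29935 probes well above background on all 9 arrays, those values differed by a median of 0.000525 from the log2 intensity minus the array's 75th percentile, centred on each probe's median over the 9 arrays, and 99.9% were within 0.01, so that scale, centring and direction could be settled from the values. Its column medians ran from -0.0397 to 0.163. The deposited table served as an alternative.

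The files pair no probe with a gene, a description or a genome position. The gene name fields repeat the probe name, the description reads "Unknown" and the coordinate "unmapped". The array carries 51093 probes in 52227 spots other than controls, with 48504 distinct sequences of 60 bases. Probes are therefore given by their identifier and sequence. Gene lists written before the data were examined, which relied on names and descriptions, could not be matched and were not tested, and the lists for other cell types fell with them. For the same reason the rule for naming genes (largest changes up and down among called genes whose groups did not overlap and that had a description) was applied without its description condition and held to 2 probes per direction and comparison. Where fewer than 2 passed, the rule's fill-in probes are not all named.

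In place of the gene lists, the probe sequences were translated in 6 frames and compared with conserved peptides of 64 plant protein families in 44 classes. These peptides were written from general knowledge, with no database at hand, after the probe table was seen and before any signal was compared between treatments. A match was an ungapped segment of at least 12 residues with a BLOSUM62 score of at least 50, a threshold set on sequences alone. Among the 51093 probes, 237 matched in a sense frame and 17 in an antisense frame, which estimates the false matches. A match places a probe in a family by resemblance and does not name its gene. Of the sense matches, 150 were tested, and 9 classes had at least 5 tested members.

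For the main setting, log2 processed intensity was shifted by each array's 75th percentile. Control spots and spots flagged as outliers were left out, and replicate spots of a probe were averaged. A probe was tested when it was well above background on all 3 arrays of at least 1 treatment, which left 33005 probes. One linear model with a mean per treatment was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), without covariates, and p-values were adjusted with the Benjamini-Hochberg method at 0.05. Peptide classes were tested with camera at a preset correlation of 0.01, adjusted over 27 tests (9 classes in 3 comparisons), and again with the correlation estimated from the arrays. A probe that was not well above background on any array of a treatment has only a bound there. For it the fold is given as "at least", from the brighter treatment's mean against the mean, over arrays, of the higher of the lowest signal well above background and the probe's own signal.

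Per the file headers, the control and deficit arrays share slide 1 and the rewatered arrays fill slide 2, which was scanned separately. Slide and treatment cannot be told apart in either comparison with the rewatered plants. Deficit against control lies within 1 slide, and its value within that slide is the fit on those 6 arrays alone. Within slide 1 all controls lie in row 1 and all deficit arrays in row 2, so row and treatment coincide there.

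The 75th percentile of intensity ran from 435 in rewatered replicate 1 to 767 in control replicate 2, and 61.1% to 68.3% of probes per array were well above background. No spot was saturated, and no pair of arrays held identical values. The number of arrays, 3 per treatment, limits the precision. The model was tested on simulated arrays with 33005 probes and 200 changed ones. In the simulated deficit against control comparison it recovered 57.5% of 2-fold and 88.5% of 4-fold changes. In the simulated rewatered against control comparison it recovered 40.0% and 88.5%, and in rewatered against deficit 58.0% and 86.5%. The simulated noise used 1 SD per probe for all 3 treatments and was independent between probes. The real median SDs between plants were unequal, at 0.0846 in deficit, 0.209 in control and 0.225 in rewatered plants. The rates are therefore not the power on the real arrays, and their differences between comparisons do not describe the treatments.

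The alternatives chosen before the data were examined were quantile or median scaling, normexp background correction with an offset of 50, 2 other filters on dim probes, the deposited table, a block for replicate number, a variance trend with robust estimation, array weights, fits on 6 arrays, stricter thresholds and leaving out each array. Testing every probe on its own is the main setting here, as no probe has a gene. A spread estimated for each treatment, 1 probe per distinct sequence, and every test of the peptide classes were chosen after the probe table was seen.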

Results

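Shoot apical meristems, the growing tips that form new leaves and stem, were taken from poplar cuttings kept for 14 days under 3 water regimes. Control plants were held at 80 to 86% of relative extractable soil water. Deficit plants were held at 17 to 23%. Rewatered plants had 9 days of deficit followed by 5 days of full watering. Each regime had 3 plants with 1 array each, and 33005 probes were bright enough to be tested. The deficit plants resembled each other most. Their median between-plant SD per probe was 0.0846 on the log2 scale, against 0.209 in control and 0.225 in rewatered plants (n = 3 each).

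**Figure D1:**
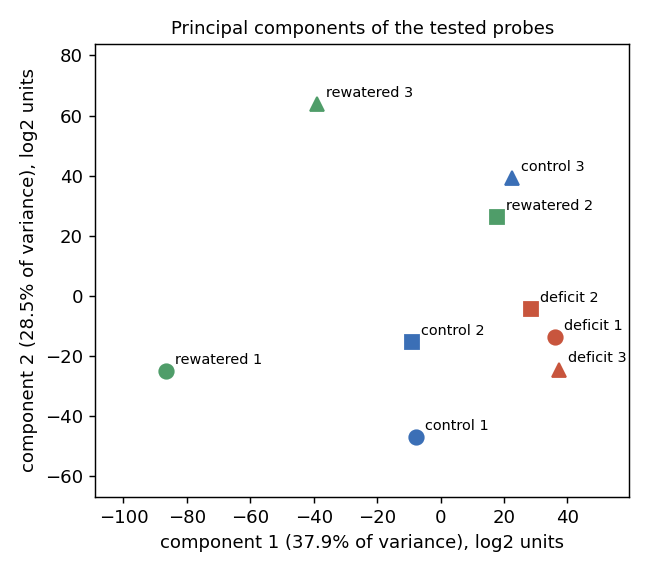
Principal components of the tested probes, with 1 point per array, colours for the treatments and shapes for the replicates. Component 1 (37.9% of the variance) and component 2 (28.5%) are in log2 units. The 3 deficit arrays lie close together, and the control and rewatered arrays are spread.

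The effect of 14 days of moderate deficit was asked by setting deficit against control plants. Of 33005 probes, 10 changed, 9 upward and 1 downward. Probe S1317 rose most, from -2.09 ± 0.20 in control to 2.04 ± 0.06 in deficit plants (log2 signal relative to the array's 75th percentile, mean ± SD, n = 3). This is a log2 change of 4.13 (SE 0.21, limma adjusted p = 0.000629), or 17.5-fold. Its sequence is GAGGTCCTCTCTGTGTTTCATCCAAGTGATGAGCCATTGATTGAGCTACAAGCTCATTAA, for which the files give neither gene nor position. Probe S77433 (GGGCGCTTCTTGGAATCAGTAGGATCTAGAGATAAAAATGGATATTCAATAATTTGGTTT, unmapped) rose from -3.05 ± 0.23 to 0.63 ± 0.05, a log2 change of 3.68 (SE 0.33, limma adjusted p = 0.0215). The only probe that fell was S27622 (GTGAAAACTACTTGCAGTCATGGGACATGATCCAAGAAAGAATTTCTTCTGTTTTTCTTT, unmapped), from -1.56 ± 0.19 to -2.93 ± 0.05, a log2 change of -1.37 (SE 0.13, limma adjusted p = 0.0231). Each of these 3 probes separated all 3 deficit plants from all 3 controls. Such separation held for 22.0% of tested probes. Of the orders of 3 against 3 arrays 10% give it, which as a chance rate presumes equal spread in both groups. The spreads differed (median SD 0.0846 in deficit and 0.209 in control plants) and probes are not independent, so the 22.0% was not tested against chance.

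**Figure D2:**
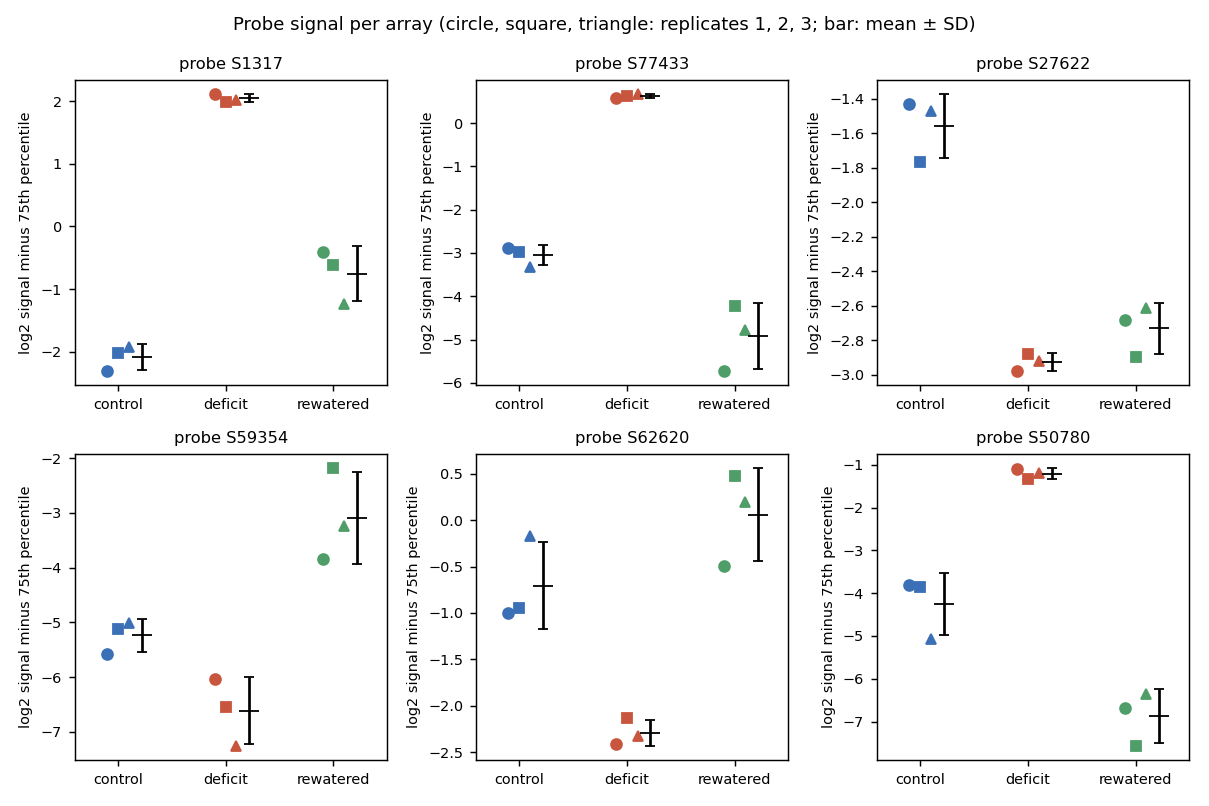
Signal of 6 probes on each array, as log2 intensity minus the array's 75th percentile. Points are single plants and bars are means ± SD of 3 plants per treatment. S1317 and S77433 stand at 2.04 and 0.63 in deficit plants, above every control and rewatered plant.

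Probes encoding kinase domains like those of receptor-like kinases, the cell-surface receptors of plants, lay higher under deficit. Of 32 tested members, 29 had a higher and 3 a lower mean, with a median log2 difference of 0.36 (camera adjusted p = 6.43e-10 at the preset correlation; adjusted p = 0.573 with an estimated correlation). Averaged over the members and relative to all 9 arrays, the class stood at 0.39 ± 0.15 in deficit and -0.08 ± 0.10 in control plants (SD, n = 3). Probes encoding peptides of laccases, oxidases that polymerise lignin in xylem walls, also lay higher, 6 of 7 members with a median of 0.63 (camera adjusted p = 0.00426; adjusted p = 0.389 with an estimated correlation). The class stood at 0.42 ± 0.07 in deficit and -0.12 ± 0.20 in control plants. Probes of heat shock proteins, which chaperone unfolded proteins, were higher in 8 of 9 members with a median of 0.16 (camera adjusted p = 0.0493; adjusted p = 0.713 with an estimated correlation). The heat shock call held in 6 of 15 alternatives and ended with quantile scaling (camera adjusted p = 0.0911) and without control replicate 1 (0.973). No single member of these 3 classes passed the test over all probes, and none did when adjusted over the list alone. SAUR probes did not pass here, and the sign of their median (0.16) differed from that of their mean (-0.28), with 2 of 6 lower when adjusted over the list alone. In all, 6 classes did not pass in this comparison. They encode calmodulin, core histones, SAUR proteins, ubiquitin-conjugating enzymes, UDP-glycosyltransferases and meristem and organ identity factors.

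Within slide 1 alone, the fit on the 6 control and deficit arrays called 52 probes, 44 higher and 8 lower. With quantile scaling the count over all arrays was 16, split 10 higher and 6 lower, and with the median shift 12, split 9 and 3. Array weights gave 11304 calls, 5224 higher and 6080 lower, and without a filter on dim probes 1 was called. The count was 1 without control replicate 1, deficit replicate 2 or deficit replicate 3, 2 without control replicate 2, 4 without deficit replicate 1, 6 without control replicate 3, and 19 without rewatered replicate 2. S1317 stayed past the threshold in all 19 of its alternatives, whereas S77433 lost it in 8 of 18 and S27622 in 8 of 19, with adjusted p up to 0.182 for both.

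What remained after rewatering was asked by setting rewatered against control plants. The limma model called 0 of 33005 probes, while 4270 had an unadjusted p under 0.05, where 1650 are expected by chance, and the smallest adjusted p was 0.189. S27622, which had fallen under deficit, stood at -2.73 ± 0.15 in rewatered plants, a log2 difference from control of -1.18 (SE 0.13, limma adjusted p = 0.189). Without rewatered replicate 1, the dimmest array, the calls were 50 higher and 57 lower probes, and the count was 19 without rewatered replicate 2. Without control replicate 3 it was 3.

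Probes encoding SAUR proteins, small products of auxin-induced transcripts, were higher in rewatered than in control plants in 6 of 6 members, which have 4 distinct sequences. Their median log2 difference was 0.82 (camera adjusted p = 0.000697; adjusted p = 0.606 with an estimated correlation). Adjusted over the list alone, 4 of the 6 passed. The class stood at 0.66 ± 0.38 in rewatered and -0.19 ± 0.57 in control plants (SD, n = 3). Control replicate 3, at 0.46, lay above rewatered replicate 2, at 0.36, so the SAUR level did not separate the plants. Probes encoding core histones, the proteins that package DNA, were higher in 11 of 12 members with a median of 0.28 (camera adjusted p = 0.0136; adjusted p = 0.713 with an estimated correlation). The class means, 0.12 ± 0.50 in rewatered and 0.02 ± 0.27 in control plants, overlapped widely, and 1 member lay at -2.15. The histone call held in 10 of 15 alternatives and ended with quantile scaling (camera adjusted p = 0.222). Receptor-like kinase probes were lower in 25 of 32 members with a median of -0.15 (camera adjusted p = 0.0493; adjusted p = 0.715 with an estimated correlation). The kinase call held in 6 of 15 alternatives and ended with quantile scaling (camera adjusted p = 0.107), with the normexp background (0.774), where the median turned to 0.04, and without rewatered replicate 3 (0.917). Slide and treatment cannot be told apart here.

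The difference between rewatering and continued deficit was asked by setting rewatered against deficit plants. Of 33005 probes, 60 changed, 35 upward and 25 downward, representing 59 distinct sequences. Of these 60, 11 were not well above background in any plant of a group. Probe S50780 (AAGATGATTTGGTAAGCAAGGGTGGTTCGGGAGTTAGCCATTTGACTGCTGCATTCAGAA, unmapped) fell from -1.20 ± 0.12 in deficit plants and was not well above background in any rewatered plant. It was at least 18.3-fold lower there (limma adjusted p = 0.00399). S77433 fell from 0.63 ± 0.05 to a level that was well above background on 1 of 3 rewatered arrays, so that no exact change is given (limma adjusted p = 0.00222). Probe S59354 (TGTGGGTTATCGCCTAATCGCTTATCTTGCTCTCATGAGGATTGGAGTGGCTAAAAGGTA, unmapped) was not well above background in any deficit plant and rose by at least 7.82-fold to -3.09 ± 0.84 (limma adjusted p = 0.0294). Probe S62620 (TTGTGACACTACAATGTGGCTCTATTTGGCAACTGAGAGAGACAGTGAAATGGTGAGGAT, unmapped) rose from -2.29 ± 0.14 to 0.06 ± 0.50, a log2 change of 2.35 (SE 0.29, limma adjusted p = 0.0294).

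In the same comparison, receptor-like kinase probes were lower after rewatering in 31 of 32 members, with a median of -0.52 (camera adjusted p = 6.43e-10; adjusted p = 0.573 with an estimated correlation). Adjusted over the list alone, 14 of them fell, and with the normexp background the median was -0.23. The class stood at -0.30 ± 0.41 in rewatered plants, with replicate 2 at 0.17 and replicates 1 and 3 at -0.56 and -0.52. Laccase probes were lower in 6 of 7 members with a median of -1.11 (camera adjusted p = 0.0271; adjusted p = 0.462 with an estimated correlation), and 4 fell when adjusted over the list alone. With the normexp background their median was -0.46. Calmodulin probes, for a calcium sensor, were lower in 6 of 6 members with a median of -1.45 (camera adjusted p = 0.0493; adjusted p = 0.713 with an estimated correlation). Their class mean was -2.68 in rewatered replicate 1 against 0.53 and 0.02 in rewatered replicates 2 and 3. The calmodulin call held in 7 of 15 alternatives and ended without rewatered replicate 1 (camera adjusted p = 0.559). SAUR probes were higher in 6 of 6 members with a median of 0.67 (camera adjusted p = 0.00192; adjusted p = 0.624 with an estimated correlation), and 2 rose when adjusted over the list alone. Core histone probes were higher in 11 of 12 members with a median of 0.41 (camera adjusted p = 0.00244; adjusted p = 0.713 with an estimated correlation), and 5 rose when adjusted over the list alone. Their class mean was 0.66 in rewatered replicate 3 but -0.32 in replicate 1, below every deficit plant, and with quantile scaling the median was 0.21. No member of any class passed over all probes.

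**Figure D3:**
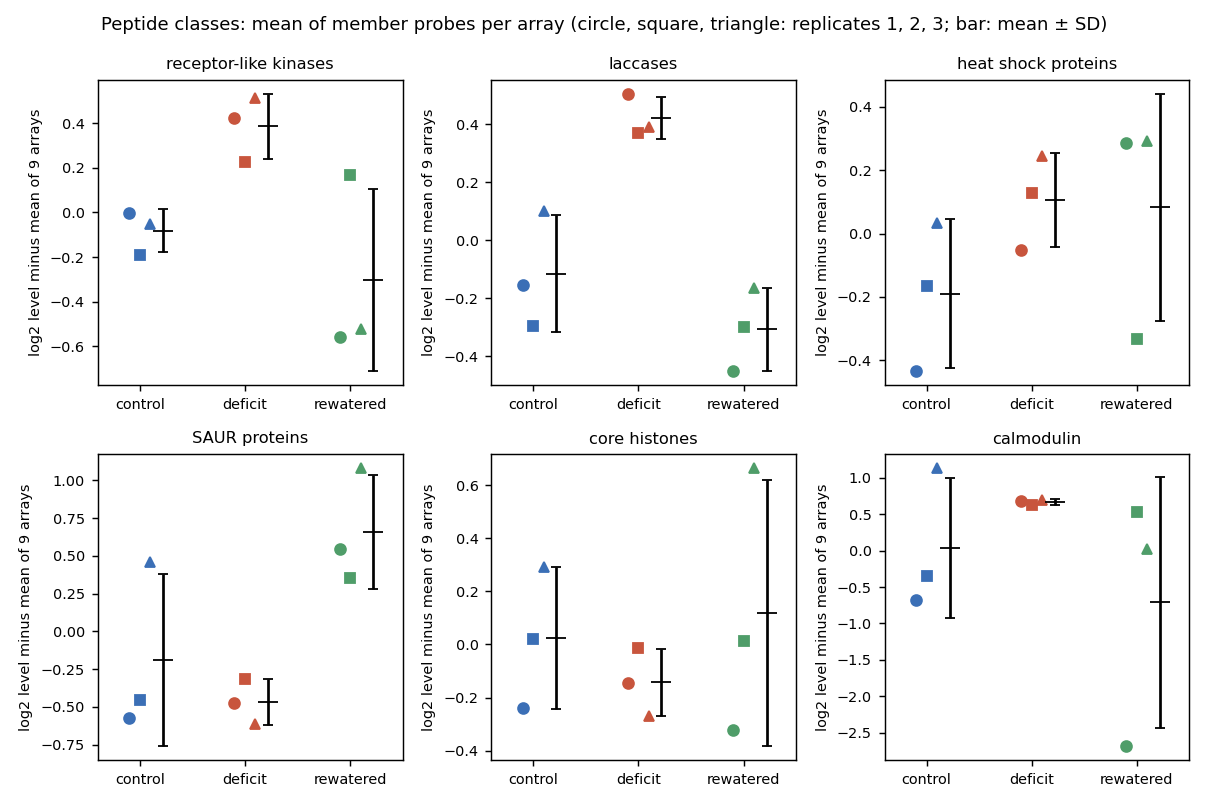
Mean level of the member probes of 6 peptide classes on each array, as log2 level minus the mean of the 9 arrays. Points are single plants and bars are means ± SD of 3 plants. Laccases stand at 0.42 ± 0.07 in deficit plants and -0.31 ± 0.14 in rewatered plants, and SAUR proteins at -0.47 ± 0.15 and 0.66 ± 0.38.

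The balance of higher and lower calls depended on the scaling. Quantile scaling gave 109 calls, 79 higher and 30 lower, of which 55 were among the 60, and the median shift 219 calls, 186 higher and 33 lower, with all 60 among them. The fit on the 6 deficit and rewatered arrays alone called 10 probes, 1 higher and 9 lower, and without a filter on dim probes 7 were called, all lower. The count was 1234 without rewatered replicate 2, 608 without rewatered replicate 1, 172 without control replicate 3, 16 without control replicate 1, 11 without rewatered replicate 3, 10 without control replicate 2, 7 without deficit replicate 1, and 4 without deficit replicate 2 or 3. S77433 passed in all 18 of its alternatives, S50780 in 17 of 18, S62620 in 10 of 19 and S59354 in 8 of 18. With the normexp background the log2 changes were -3.28 for S77433, -2.02 for S50780 and 1.11 for S59354, and for S50780 and S59354 these are smaller than the bounds above. Slide and treatment cannot be told apart in this comparison either.

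Over the 3 treatments together, the limma F test called 20 probes. Of the 10 probes changed under deficit, 7 also changed in the opposite direction between deficit and rewatered plants. Of the 10, 4 were not well above background in any plant of a group. Both comparisons use the deficit arrays, so that unchanged groups can give such turns as well. The F test count was 1 without deficit replicate 2 or deficit replicate 3, 4 without control replicate 1, 5 without control replicate 2 or deficit replicate 1, 13 without rewatered replicate 3, 47 without control replicate 3, 251 without rewatered replicate 2 and 307 without rewatered replicate 1. The count turned back was 15 with the normexp background, 14 without rewatered replicate 2, and 1 without control replicate 1, deficit replicate 2 or deficit replicate 3. It was 2 without control replicate 2, 3 without rewatered replicate 3 and 4 without deficit replicate 1. At least 7 probes turned back in 2 of the 100 simulations, and at least 10 were called for deficit against control in 11.

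Across all tested probes, the changes of deficit and rewatered plants against control had a covariance of -0.000778 and a Pearson correlation of -0.00784 across probes, which are not independent replicates. Unchanged groups that share the 3 controls gave a mean covariance of 0.0359 in 1000 simulations (95% between -0.00451 and 0.159) and a mean correlation of 0.475. The observed covariance lay 0.0367 below the simulated mean but within that range. No probe was called in both comparisons, and with 0 calls in one of them 0 are expected of independent lists. With 3 controls, 1 part would hold under 2 arrays, so the controls were not split.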

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

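The test on probes of identical sequence, that on spike-in controls, that on open reading frames and that on near-copies were set out before their results were seen. The others here were chosen after.

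Laccase and SAUR probes stood out because every deficit plant lay on one side of the control mean and every rewatered plant on the other. Not all single controls lay between them. For laccases they were at -0.15, -0.29 and 0.10, with replicate 2 among the rewatered plants and replicates 1 and 3 between the groups. For SAUR they were at -0.58, -0.46 and 0.46, with replicates 1 and 2 among the deficit plants and replicate 3 among the rewatered plants. Laccases did not pass in rewatered against control (camera adjusted p = 0.665), nor SAUR in deficit against control (0.642). For laccases the class mean was 0.727 higher in deficit than in rewatered plants on the log2 scale. For SAUR proteins the deficit mean minus the rewatered mean was -1.13, whereas the member median in rewatered against deficit was 0.67. The SAUR class mean hides a split in deficit against control. There 4 of the 6 members, which have 4 distinct sequences, were higher and 2 lower, with a median of 0.16. The difference itself was tested as rewatered against deficit, with camera adjusted p = 0.0271 for laccases and 0.00192 for SAUR proteins. Neither call held in the test with an estimated correlation (adjusted p = 0.462 and 0.624). That correlation was 0.749 for SAUR proteins but -0.0517 for laccases, below the preset 0.01. The laccase call was therefore not ended by a higher correlation between its members.

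Receptor-like kinase probes were higher under deficit and lower after rewatering. A general shift of coding sequence, as a difference in RNA quality could give, stays open. Probes with an open reading frame differed from those without one by a median of only 0.0294 in deficit against control. However, 1 stop-free frame of 3 was enough, and 24563 of 33005 probes had one, so the mark separates coding sequence poorly. Near-copy probes did not carry the class. The 30 of 32 members with less than 75% identity to another member had a median of 0.388 in deficit against control. Leaving out so few members could hardly move the median. Only the probe sequences were compared, so members that read different stretches of the same few transcripts stay open. Differences between single plants along an axis that the class shares remain open, as the adjusted p with an estimated correlation was 0.573 with 3 plants per group. An effect of deficit also remains open, and row on the slide and treatment cannot be told apart.

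The deficit plants differed less from each other than the other plants did. Lower measurement noise on their arrays is argued against, because probes of identical sequence differed within an array by 0.987 times as much on deficit arrays as on the others (95% bootstrap interval 0.943 to 1.03 over 1372 pairs). More even labelling stays open, as the spike-in controls varied 0.827 times as much in the deficit group, which meets the bound of 0.8 set beforehand for arguing against it, but with 8 of them the interval, added after the ratio was seen, ran from 0.410 to 2.28 and left it open. A single stray array is argued against in the rewatered group, where even the closest pair differed 2.06 times as much as the widest deficit pair, but stays open in the control group, at 1.196 times for replicates 1 and 2. A more uniform state of the meristem under sustained deficit remains open and was not tested.

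The rewatered against control comparison called 0 probes, but another split of the same 6 arrays called 631. That split exchanges control replicate 3 and rewatered replicate 1. So many calls may point to a structure of the samples that crosses treatment and slide. The split was picked out as the highest of 10 and was not tested against chance. Array brightness did not order the sides of that split. By the 75th percentile, control replicates 1 and 2 (691 and 767) were brighter than rewatered replicates 2 and 3 (634 and 633) on the other side. The brightest array of their side was 1.00 times as bright as the brightest on the other. Only rewatered replicate 1 (435) was dimmer than the whole other side, and an effect of that 1 dim array stays open. Exchanged labels may be considered and stay open, as control replicate 3 lay 1.30 times as far from its own group as from the other rewatered plants, but rewatered replicate 1 only 1.05 times. Differences between plants in the stage of the isolated apex were not tested.

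For deficit against control, 1 of the 10 splits of the 6 arrays, the real one, gave 10 or more calls, and the highest other gave 0. For rewatered against control all 10 splits gave at least the real 0. For rewatered against deficit, 1 of 10 reached 60, with 0 as the highest other. For the peptide classes, 4, 7 and 3 of 10 splits reached the real 3, 3 and 5 classes, with 4, 6 and 5 as the highest others. Splits of 3 against 3 are too few for a share under 0.05. For the peptide classes their number is not the only limit, since other splits reached the real counts in every comparison. Chance is therefore not excluded for the class counts at the preset correlation.

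Over all 3 groups, 2 of 100 splits drawn from 280, the real one included, gave 20 or more F test calls, a share under 0.05. The other, which exchanges control replicate 3 and rewatered replicate 1, gave 335. It is the same exchange on the same arrays as above, so it is not separate evidence for a structure of the samples. Only drawn splits that keep the 3 deficit arrays together gave any calls, and these arrays also share a row of slide 1. The share may therefore reflect the likeness of the deficit arrays and does not show an effect of each treatment. The count of probes turned back and the covariance depend on which group has which role, so 100 assignments were drawn from 1680, after a first draw that had not varied the roles. Of those drawn, the real one alone reached 7 probes turned back, with 0 as the highest other, a share under 0.05. The draw missed the real grouping with the control and rewatered roles swapped, which also gave 7. The count does not change under that swap, so it does not show that the probes returned to control levels. The draw missed the exchanged split as well, which gave 12 to 53 over its 6 assignments of roles, so the share says little about that structure. A covariance of at least -0.000778 came from 97 of the 100, with 0.136 as the highest other. That count looks at high values, whereas the observed covariance lay below the simulated mean, so it cannot decide whether the covariance was low. The lower ones drawn were -0.00259, -0.00171 and -0.00157. Of the 1000 simulations of unchanged groups, 62 gave a covariance as small, so that chance is not excluded by those simulations.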

How the results depend on the processing

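Results are given as probes called in deficit against control, rewatered against control and rewatered against deficit, then by the F test, then turned back, with 10, 0, 60, 20 and 7 in the main setting. Quantile scaling gave 16, 0, 109, 49 and 12. The median shift gave 219 for rewatered against deficit and 55 in the F test. Normexp gave 22, 0, 123, 43 and 15. Without a filter on dim probes the counts were 1, 1, 7, 5 and 1, with more probes to adjust over. With probes well above background on all 9 arrays deficit against control had 6 and 3 turned back. The variance trend also gave 6 there. Array weights gave 11304 and 132 in deficit against control and rewatered against deficit, and a spread estimated for each treatment 34 and 184 in these comparisons and 35 in the F test. Fits on 6 arrays gave 52 and 10 in these, and an adjusted p below 0.01 gave 1 and 7. Leaving out single arrays gave 1 to 19, 0 to 1.1e2 (50 higher and 57 lower), 4 to 1234, 1 to 307 and 1 to 14. The covariance of the changes against control ran from -0.0187 to 0.0452 without single arrays. The deposited table and 1 probe per distinct sequence moved no count by over 1.5 times. Apart from fewer probes, fewer arrays or a stricter threshold, the cause was not tested.

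With replicate number as a block, the counts were 2, 0, 1, 3 and 0, and the classes called 3, 4 and 5. The deviations of same-numbered plants from their group means correlated between -0.253 and 0.437 and were of both signs, so the numbers were not taken to pair the plants.

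Peptide classes called numbered 3, 3 and 5 in the main setting. The test with an estimated correlation left 0, 0 and 0, also for laccases, whose estimated correlation of -0.0517 lay below the preset one. Normexp left 1 for rewatered against control. Without single arrays they were 2 to 5, 2 to 5 and 3 to 5. The receptor-like kinase calls held in 14 of 15 alternatives in deficit against control and in rewatered against deficit, but in 6 of 15 in rewatered against control. Those 14 all kept the preset correlation of 0.01. The estimated one was 0.398 for this class and ended both calls (camera adjusted p = 0.573 in each). Heat shock proteins in deficit against control held in 6, calmodulin in rewatered against deficit in 7 and core histones in rewatered against control in 10. Of the named probes none changed sign, though normexp shrank S50780 to -2.02, S59354 to 1.11 and S77433 to -3.28 in rewatered against deficit. These 3 values include the offset in groups where the probes were dim and are not exact changes. Testing every probe on its own equals the main setting, and the name-based gene lists were not run. Signal limits dim probes, since 31.7% to 38.9% of probes per array were not well above background.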

Other observations

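The class tests and the correlation between probes of one sequence were chosen after the probe table was seen, and no hypothesis is added here.

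Probes that encode meristem and organ identity factors (MADS, LBD, SBP and YABBY domains among the matches) were higher in rewatered than in control plants in 9 of 11 members, with a median log2 difference of 0.29 (camera adjusted p = 0.0523, adjusted p = 0.713 with an estimated correlation), which did not pass. The class passed in 6 of 15 alternatives, among them quantile scaling (camera adjusted p = 0.0473) and the median shift (0.0494). Probes of UDP-glycosyltransferases and of ubiquitin-conjugating enzymes passed in none of the 3 comparisons, with camera adjusted p of 0.375 or more.

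In deficit plants 98 probes were well above background on all 3 arrays and on no control array, against 22 the other way round. Between rewatered and deficit plants the numbers were 24 detected only after rewatering and 72 only under deficit, and between rewatered and control plants 10 and 23. Deficit plants, which differed least from each other, also had the most probes well above background on all 3 arrays, 32610 against 31924 in control and 30225 in rewatered plants. The log2 changes of probes that share a sequence correlated across 1492 sequences at Pearson r = 0.835 for deficit against control and 0.883 for rewatered against deficit, across probes that are not independent replicates.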
